A study of Mus musculus with 12 samples.

How the data were processed

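Hypothalamic tissue enriched for the arcuate nucleus was dissected from POMC-RiboTag mice, a line in which a tagged ribosomal protein is made in neurons of the pro-opiomelanocortin (POMC) lineage. Per the labels' protocols, tagged ribosomes were pulled down with an antibody against the HA tag. RNA was recovered from the beads, and cDNA was amplified from under a nanogram of RNA with a low-input kit before tagmentation into sequencing libraries. Only RNA of high integrity entered sequencing, per the labels. The mice had been fasted for 16 h and habituated to the room for 1 h. They were then shown for 10 min either chow behind wire mesh (the SENS group, food that could be sensed but not eaten) or a wooden object of like size behind mesh (the NEO group, a nonedible object). All exposures took place around zeitgeber time 6 h. There were 6 libraries in each group. The labels do not say whether each library came from a separate mouse, so p-values measure only the spread between these libraries, which could be partly technical.

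The authors deposited 1 table of CPM values (read counts scaled to a common column total) with 5764 genes and 12 library columns, all of which were used. FastQC, HISAT2, featureCounts and edgeR, and the mouse builds GRCm38 and mm10, are named per the submitters' processing notes, which give no versions, roles or order in the sources used here. The filter that selected these genes, the use of strand and the treatment of reads matching several places are not given in the sources used here. Each deposited CPM column summed to between 999936 and 1000000, so the values are relative to the reads in the genes of this table and not to all reads of a library. The most frequent value above 0 in each column was taken as the worth of 1 read. On that scale 100% of the values above 0 were multiples of a hundredth of a read (tolerance 0.0002 reads), and 81.2% were whole reads (tolerance 0.005 reads). The remaining 18.8% were fractions such as those made when a read is shared among several genes. Because too few values were whole reads, no count model was fitted.

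The reads behind the table came to between 6901 and 18299 per library, so 1 read was worth between 54.6 and 145 CPM. A value of 0 in a library allows a level of up to 3 reads, which corresponded to between 164 and 435 CPM per library. Over all 6 libraries of a group this limit was 58.8 CPM for NEO (51054 reads) and 38.2 CPM for SENS (78624 reads). These totals are reads in the genes of this table, not the depth of the libraries, which is unknown. Reads were not marked by molecular identifiers, so limits from a count of 0 cover counting error only.

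Gene symbols were used as the table gives them. A RefSeq annotation of GRCm38.p6 held 5728 of the symbols (99.4%), and gene types and coordinates come from it.

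The comparison of SENS with NEO was fitted with limma 3.58.1 in R 4.3.3 (linear model, moderated variance with a trend) on log2(CPM + 1). Genes with a mean of at least 1 CPM over all libraries entered, no covariate was used, tests were two-sided, and Benjamini-Hochberg adjusted p-values under 0.05 were called. Fold changes are on the log2(CPM + 1) scale, and where a library is at 0 they depend strongly on the pseudocount. They can then lie far above the ratio of the mean CPM. Adjusted p-values of single genes come from this limma fit. The members of 26 gene lists and their tests were set before the data were examined. Lists with at least 5 measured members were tested with limma's camera (preset correlation 0.01), with camera at an estimated correlation, and with fry, which asks whether the members of a list move one way on balance. After the gene names and part of the values had been seen, 17 further lists were written for the kinds of gene the table does hold. Leading genes already seen were left out of them (among them F13a1, Galp, Ddias and Gnrh1), but Oas1a, Snord16a and Chat had been seen and were kept. Library measures, summed CPM of lists and mean marker levels were compared with two-sided exact permutation tests over all 924 regroupings. Reads were thinned to 6000 per library (mean of 20 draws) to compare the number of genes at an equal number of reads in the genes of this table.

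Named genes followed a rule written at the same stage as the lists. It took all measured glycogen genes, the genes Pomc, Cartpt, Agrp, Npy and Fos, and the 10 named genes per direction with the smallest unadjusted p where no gene passed. It also took up to 4 members of every other list set beforehand. The 5 genes of the second part are not analysed here, since the table used holds no value for them. From each added list the 2 members with the smallest unadjusted p were taken, a rule made after the data were seen. One gene that this rule took is not reported here and was not replaced; it stays in the fits and list tests. Galp and Gnrh1 were chosen after their values were seen.

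The limma fit was tested on simulated data of this size with 200 genes changed. These 200 were drawn from genes with a mean of at least 1 read per library, while the median gene of the table had a mean of 0.75. With the spread of the real libraries, none of the genes changed 4-fold were recovered (4712 genes tested), 0.5% of those changed 8-fold (4752 genes) and 6% of those changed 16-fold (4703 genes). This spread was the median over genes with a mean of at least 1 read per library. It came from reads not scaled to library totals, in genes kept by an unknown filter, so it may be too large. With counting noise alone, 31.5% of the genes changed 4-fold were recovered (4737 genes) and 81% of those changed 16-fold (4760 genes). In that 16-fold run, 33 of the 195 calls were unchanged genes. Each simulated column was rescaled to a common total after the changes, which shifts the CPM of unchanged genes between the groups. These 33 calls thus do not show whether the fit calls too many. Other settings chosen before the data were examined were pseudocounts of 0.1 and 5, no filter and a filter at a mean of 10 CPM, quantile and trimmed-mean scaling, other variance models, library weights, a block for the replicate number or the label number range, and each library left out in turn. Pseudocounts of 50, 100 and 200, filters at a mean of 100 and 200 CPM, and the fit without NEO 4 and SENS 6 were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the remaining steps.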

Results

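RNA pulled down with tagged ribosomes was compared between fasted mice that sensed food for 10 min and fasted mice shown a nonedible object. The tag is made in the lineage of POMC neurons, arcuate neurons that make the appetite-suppressing peptide α-MSH. No input or untagged library was among the 12, so background of the pull-down cannot be told apart from RNA of these neurons. The series title ties the comparison to glycogen metabolism in the activation of these neurons. Each group had 6 libraries. The table held genes of low abundance, with a median of 9 reads per gene over all 12 libraries and a highest mean of 14.3 reads per library. It contained 3636 protein-coding genes, 1340 long noncoding RNA genes, 496 microRNA genes and 98 small nucleolar RNA genes. Of the 5764 genes, 621 were at 0 in every library and 232 were above 0 in every library. No gene had 10 or more reads in all 6 libraries of either group. Pomc, Cartpt, Agrp, Npy and Fos are not analysed here.

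The NEO libraries held 10233, 11139, 7151, 7885, 6901 and 7745 reads in these genes (replicates 1 to 6), and the SENS libraries 8619, 15589, 13338, 10739, 12040 and 18299. The mean was 8509 ± 1749 reads in NEO and 13104 ± 3466 in SENS (SD, n = 6 each), 1.54-fold higher in SENS. A two-sided exact permutation test gave p = 0.0130, and 0.0779 after adjustment over 6 library measures. The labels carry library numbers that fall into 3 ranges, each with as many NEO as SENS libraries. The difference was 4497 reads among the 6 libraries numbered 1062 to 1074 and 7847 among the 4 numbered 1103 to 1116. It was −1614 in the remaining range, which held 1 library per group. Regrouping within the ranges gave an exact permutation p = 0.0333. Genes above 0 numbered 1894 ± 328 in NEO and 2137 ± 300 in SENS (SD, n = 6 each; exact permutation p = 0.210, adjusted p = 0.420). At 6000 reads per library they numbered 1599 ± 251 and 1648 ± 255 (exact permutation p = 0.740, adjusted p = 0.855).

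**Figure D1:**
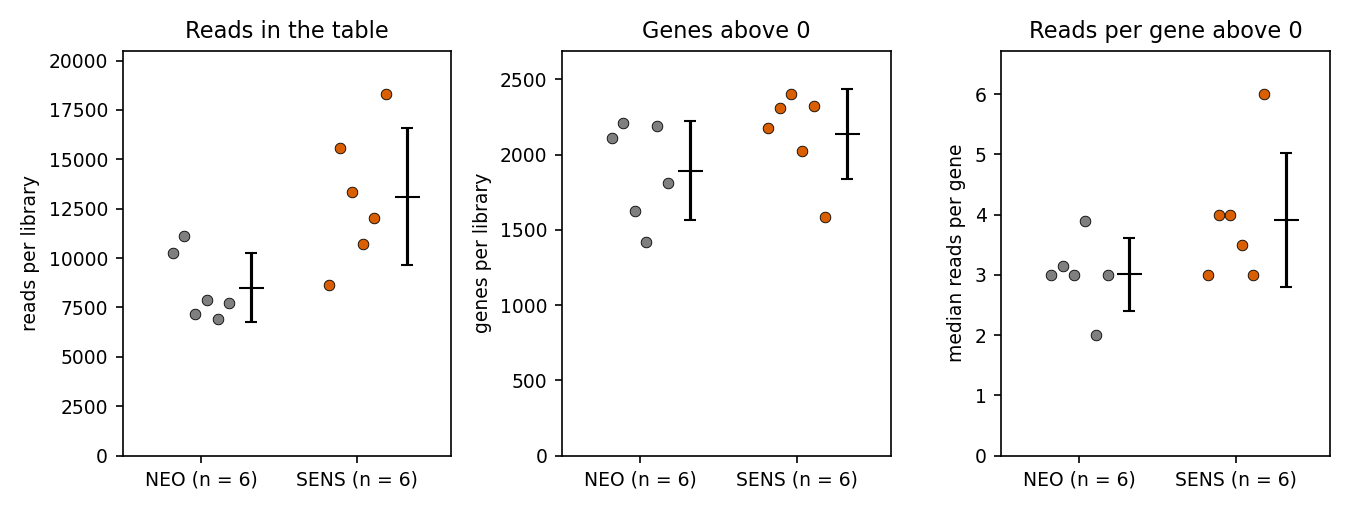
Reads in the table, genes above 0 and median reads per gene above 0 for each library (points), with the group mean and SD (bars, n = 6 each). SENS 6 had the most reads (18299) and, of the SENS libraries, the fewest genes above 0 (1589).

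The comparison of SENS with NEO asked which of these transcripts differed in level in the pulled-down RNA after food was sensed. No gene passed: limma called 0 of 5141 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.728. This count says nothing about genes with higher levels in either group, which are not analysed here, since no gene tested had 10 or more reads in all 6 libraries of a group. At an unadjusted p under 0.05 there were 189 genes (94 higher and 95 lower in SENS), and 99 other splits of the same libraries into groups of 6 had a median of 169 (113 to 284). The balance of directions depended on the libraries and the variance model: it was 57 higher and 113 lower without NEO 4, 107 and 70 without SENS 6, and 149 and 100 without a variance trend. The median log2 fold change over all genes was 0.39, and the median SE of a log2 fold change was 1.82. In the simulated data with the spread of these libraries, this fit rarely recovered changes of 8-fold or less. No other fit was simulated.

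The named gene with the smallest unadjusted p among those with higher values in SENS was F13a1, the A subunit of coagulation factor XIII (chromosome 13, 36867178 to 37050244, GRCm38). Its mean was 205 ± 413 CPM in NEO, where 2 of 6 libraries were above 0 and NEO 6 held 8 of 10 reads, and 1169 ± 631 CPM in SENS, where all 6 were (SD, n = 6 each; log2 fold change 7.05, SE 2.04, limma adjusted p = 0.728). Col14a1, a collagen associated with fibrils, had 388 ± 686 and 1075 ± 732 CPM. Zic1, a zinc finger transcription factor, had 143 ± 186 CPM in NEO and 1397 ± 1895 CPM in SENS, where SENS 2 alone held 81 of 116 reads. Stag3, a subunit of the meiotic cohesin complex, had 1 read in NEO and 53 reads in 5 SENS libraries. Txndc2, a thioredoxin of sperm cells, had 0 of 51054 reads in NEO and 17 reads in 5 SENS libraries. Its pooled SENS level was 3.68 times the NEO limit of 3 reads, and 2.88 times without NEO 2. This ratio leaves out the error of the 17 reads and the spread between libraries, and the gene did not pass. The interleukin 21 receptor gene Il21r, the imprinted noncoding gene Hymai, Xlr, the homeobox gene Hlx and the sulfotransferase gene Chst3 completed these 10. Each had a higher mean CPM in SENS and an adjusted p = 0.745. Xlr carried fractional reads, which could come from sharing with related copies (not tested), so its value is uncertain.

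Among named genes with lower values in SENS, the pigment cell receptor gene Gpr143 had the smallest unadjusted p (chromosome X, 152781921 to 152808651). It had 1846 ± 1008 CPM in NEO and 295 ± 422 CPM in SENS (SD, n = 6 each; log2 fold change −6.10, SE 1.61, limma adjusted p = 0.728), with 94 against 18 reads. Ddias, a suppressor of apoptosis after DNA damage, had 2265 ± 1615 and 371 ± 576 CPM. Pitx3, a homeobox gene of lens and midbrain dopamine neurons, had 1471 ± 794 and 288 ± 320 CPM. Both had an adjusted p = 0.728. Rpl3l, a ribosomal protein gene paralog of striated muscle, had 37 reads in 6 NEO libraries and 4 reads in 1 SENS library. The growth factor gene Fgf20 had 974 ± 474 and 422 ± 784 CPM, and 26 of its 31 SENS reads lay in SENS 3. Cyp2j12, Plekha4, Nutm1, the meiotic gene M1ap and the testis kinase gene Tssk3 completed this set. Each was above 0 in all 6 NEO libraries and in 2 or 3 SENS libraries, with an adjusted p = 0.745. Galp, which encodes the arcuate neuropeptide galanin-like peptide and was chosen after its values were seen, had 1229 ± 678 CPM in NEO and 434 ± 536 CPM in SENS (SD, n = 6 each). Its log2 fold change was −4.12 (SE 1.38, limma adjusted p = 0.745).

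**Figure D2:**
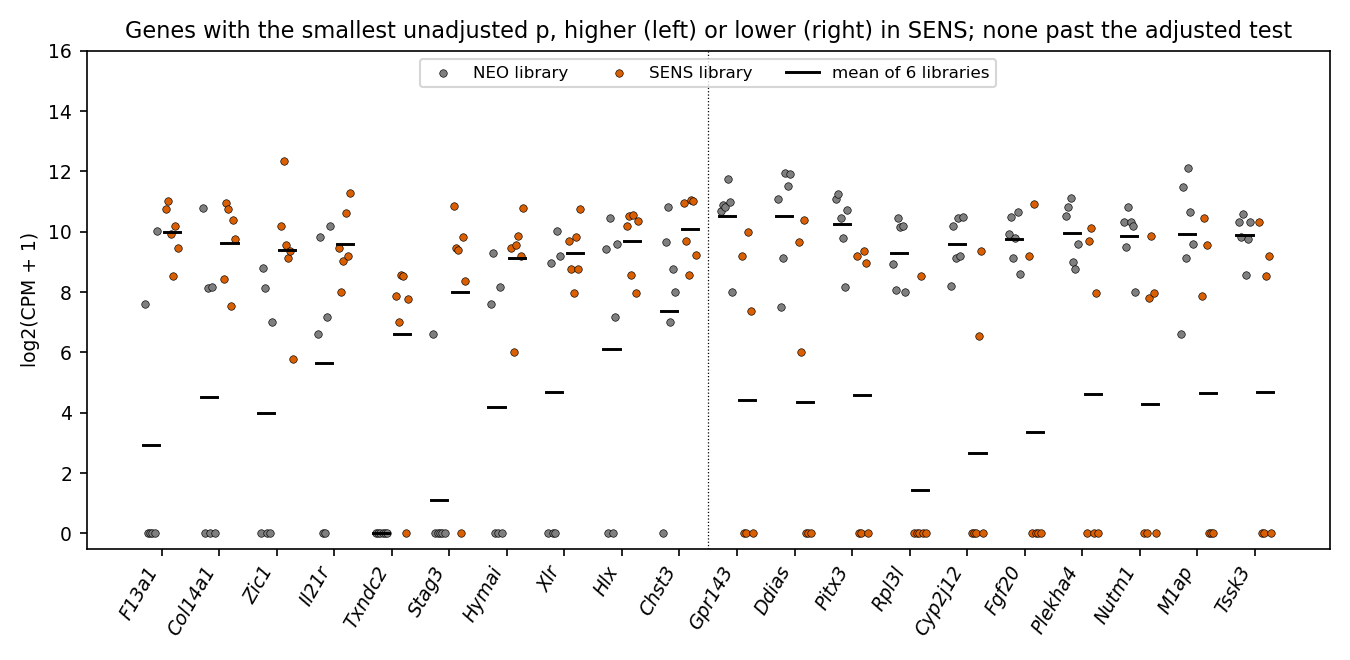
log2(CPM + 1) of the 10 named genes per direction with the smallest unadjusted p, in each NEO (grey) and SENS (orange) library, with group means (lines, n = 6 each). Most group differences come from libraries at 0 in 1 group, as for Txndc2, which was at 0 in all NEO libraries.

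Of the 31 glycogen metabolism genes listed beforehand, the table held 1, Gys2, the liver form of glycogen synthase (chromosome 6, 142422612 to 142473130). It had 0 of 51054 reads in NEO and 5 of 78624 reads in SENS, all 5 in SENS 5. The pooled SENS level of Gys2 was only 1.08 times the NEO limit of 3 reads. The log2 fold change of Gys2 was 1.45 (SE 1.34, limma adjusted p = 0.745). The remaining listed genes of the pathway, such as the brain form of glycogen synthase and the glycogen phosphorylases, are not analysed here. Of the 41 immediate early and activity-regulated genes, the table held Fosl1, a Fos family transcription factor, with 378 ± 442 CPM in NEO and 208 ± 275 CPM in SENS (SD, n = 6 each). Its log2 fold change was −0.73 (SE 2.52, limma adjusted p = 0.958), and its sign turned when NEO 3 (0.10), NEO 4 (0.069), SENS 1 (0.29) or SENS 6 (0.29) was left out. With 1 member each, neither list had a set test, and adjusted over the list alone both counts were 0.

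Other genes of the lists set beforehand were few. Chat, the acetylcholine synthesis enzyme, had 812 ± 808 CPM in NEO and 294 ± 338 CPM in SENS. Rpl39l, a ribosomal protein paralog, had 865 ± 821 and 209 ± 330 CPM. Ndufs5, of respiratory complex I, had 1 read in NEO 6, and the glutamate receptor gene Grm6 had 1 read in SENS 3. In all, 18 of the 26 lists had no gene in the table and 6 had 1 to 4.

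Markers of blood cells (6 genes) and of the pituitary (7 genes) were the lists with enough members for a set test. Neither differed in camera (adjusted p = 0.714 for both, and 0.760 for both with an estimated correlation), fry gave an adjusted p = 0.690 for both, and 0 members passed over all genes or adjusted over the list alone. Adjusted over the list alone, 1 blood cell marker passed without SENS 6, and without both NEO 4 and SENS 6. Both lists had medians below 0 (−0.15 for both) and means above 0 (0.21 for blood cells and 0.40 for the pituitary), while camera placed blood cell markers lower and pituitary markers higher. Ptprc, the leukocyte marker CD45, had 469 ± 564 CPM in NEO and 1498 ± 1358 CPM in SENS, and the lymphocyte gene Cd52 had 791 ± 464 and 920 ± 770 CPM. The haemoglobin gene Hba-a1 had 1 read and the erythrocyte gene Slc4a1 had 2 reads, all in NEO. The prolactin gene Prl had no reads in NEO and 53 in SENS, 52 of them in SENS 4. Tshb, the β subunit of thyrotropin, had 14 reads in NEO and 47 in SENS (31 of them in SENS 3), and Lhb, the β subunit of luteinizing hormone, had 22 and 46. Cd52 and Tshb had log2 fold changes of −1.20 and −1.87, opposite to their mean CPM, which was higher in SENS. Pou1f1, a pituitary transcription factor, had at most 0.4 reads in any library. The mean log2(CPM + 1) of blood cell markers was 4.45 ± 1.78 in NEO and 4.66 ± 1.31 in SENS, and that of pituitary markers 3.27 ± 0.76 and 3.67 ± 2.05 (SD, n = 6 each). Exact permutation tests gave p = 0.820 and 0.662, both 0.820 after adjustment. The remaining 8 marker lists of other cell types had no gene in the table.

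Among the 17 lists written after the gene names were seen, camera called 3, relative to the other genes. The median log2 fold change of all genes was 0.39, and it was larger without NEO 1 (0.64), NEO 2 (0.72) or NEO 5 (0.71). Keratins, the intermediate filaments of epithelia, were lower in SENS for 19 of 27 members (median log2 fold change −1.40, mean −1.36, camera adjusted p = 0.00322), with adjusted p = 0.229 with an estimated correlation. Krt28 had 871 ± 410.5 CPM in NEO and 341 ± 355 CPM in SENS, and Krt86 had 7.74 reads in NEO, 6 of them in NEO 4, and none in SENS. These keratin genes carried fractional reads, which could come from sharing with related copies (not tested), so their values are uncertain. Small nucleolar RNA genes were higher for 59 of 79 members (median 1.15, mean 1.23, camera adjusted p = 0.0122), with adjusted p = 0.794 with an estimated correlation. Snord16a had no reads in NEO and 12 in 5 SENS libraries, and Snord53 none and 17, of which SENS 6 held 13. Vomeronasal receptors were lower for 35 of 63 members (median −0.53, mean −0.56, camera adjusted p = 0.0403), with adjusted p = 0.287 with an estimated correlation. Vmn2r2 had 454 ± 498 CPM in NEO and 98.8 ± 112 CPM in SENS, and Vmn2r5 had 184 ± 117 and 30.9 ± 42.6 CPM. Both carried fractional reads, which could come from sharing among near-identical receptors (not tested), so their values are uncertain. Many small nucleolar RNA genes lie inside host genes, and their reads were not told apart from those of the host. In this fit no list had a member that passed over all genes or adjusted over the list alone. Without a variance trend 1 small nucleolar RNA gene passed adjusted over the list alone. In the fit to all libraries fry gave no adjusted p below 0.521.

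The keratin call held with each library left out in turn and was lost with a mean of at least 200 CPM (adjusted p = 0.0845), as were the other 2 (0.331 for both). The small nucleolar RNA call was lost without NEO 4 (adjusted p = 0.0846), NEO 5 (0.436), SENS 5 (0.227) or SENS 6 (0.0600), and with a mean of at least 100 CPM (0.0652). The vomeronasal call was lost without NEO 1 (0.0557), NEO 3 (0.103), NEO 4 (0.0969), NEO 6 (0.135), SENS 2 (0.0878), SENS 4 (0.0737) or SENS 6 (0.0600), and with a pseudocount of 0.1 (0.0813) or a block for the label number range (0.0586). The summed CPM of vomeronasal receptors was 5410 ± 1188 in NEO and 3106 ± 1075 in SENS (SD, n = 6 each; exact permutation p = 0.0108, adjusted p = 0.184 over the 17 lists). For keratins it was 6415 ± 2642 and 3911 ± 1862 (exact permutation p = 0.0758, adjusted p = 0.451), and for small nucleolar RNA genes 9011 ± 5336 and 13815 ± 9104 (exact permutation p = 0.286, adjusted p = 0.685). Single libraries weighed on both. The keratin difference of −2504 CPM became −1464 without NEO 6 (11619 CPM; unadjusted exact permutation p = 0.134) and −3253 without SENS 5 (p = 0.00649), and p ranged from 0.00649 to 0.222 over all settings tried. The small nucleolar RNA difference of 4804 CPM became 1470 without SENS 5 (30487 CPM; exact permutation p = 0.608). The vomeronasal difference lay between −2602 and −1760 CPM over all settings tried, with unadjusted exact permutation p from 0.00649 to 0.0397. In reads, vomeronasal receptors had 269 in NEO and 234 in SENS, keratins 322 and 302, and small nucleolar RNA genes 504 and 1109. All genes of the table had 51054 and 78624 reads. CPM are relative to these totals, so lower CPM of a list cannot be told apart from a rise of other genes in the table.

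**Figure D3:**
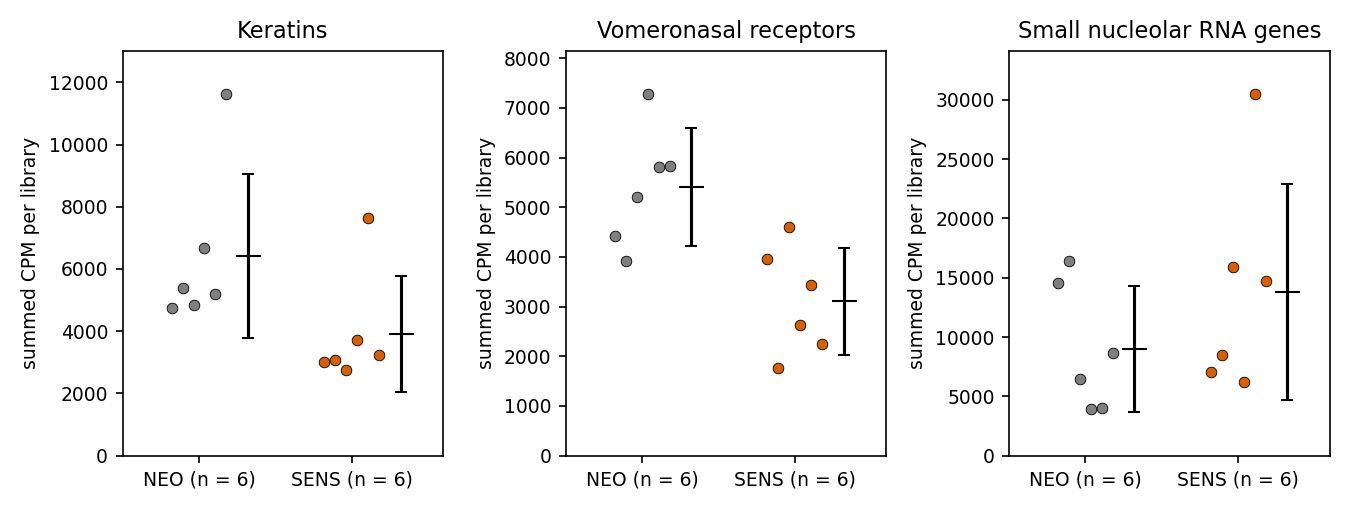
Summed CPM of keratins, vomeronasal receptors and small nucleolar RNA genes in each library (points), with group mean and SD (bars, n = 6 each). The groups overlap for each list, as with keratins, where SENS 5 (7654 CPM) lies above NEO 4 (6679 CPM).

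The other 14 of these lists were not called by camera in the fit to all libraries. The median log2 fold change of all genes was 0.39, so a list with most members higher need not differ from other genes. Sperm and testis genes had higher values in SENS for 29 of 38 members (median 1.29, camera adjusted p = 0.0930, and 0.794 with an estimated correlation). Other settings did call this list. Camera called it with pseudocounts of 50, 100 and 200 (adjusted p = 0.0208, 0.0158 and 0.0128), a mean of at least 100 CPM (0.0177), quantile scaling (0.0444), and without SENS 2 (0.0429) or SENS 3 (0.0440), and over all settings its adjusted p ranged from 0.0128 to 0.510 (without SENS 1, where 20 of 32 members were higher). Its summed CPM was 7481 ± 2674 in NEO and 11725 ± 4877 in SENS (SD, n = 6 each; exact permutation p = 0.106, adjusted p = 0.451). Fry called it with a mean of at least 100 CPM (adjusted p = 0.000671) and of at least 200 CPM (0.00261), with a range from 0.000671 to 0.712. Camera with an estimated correlation gave adjusted p-values between 0.127 and 0.984. Spata48 had 152 ± 85.2 CPM in NEO and 589 ± 252 CPM in SENS, and Tex47 had no reads in NEO and 36 in SENS, 30 of them in SENS 6. Chemokines and interleukins had lower values for 22 of 34 (adjusted p = 0.313), with the interleukin gene Il1a at 119 ± 191 and 746 ± 685 CPM and Il17b at 660.3 ± 452 and 327 ± 374 CPM. Monoamine, acetylcholine and glycine transmission genes were lower for 5 of 10 (adjusted p = 0.487), and the dopamine receptor gene Drd4 had 11 reads in NEO and none in SENS, the noradrenaline transporter gene Slc6a2 none and 18.4 (10.2 of them in SENS 5). MicroRNA genes were higher for 221 of 358 (adjusted p = 0.502), with Mir341 at 7 reads and Mir93 at 4 reads in SENS and none in NEO. Their pooled SENS levels were 1.52 and 0.866 times the NEO limit of 3 reads, so 0 reads in NEO show little. Genes of gluconeogenesis and sugar transport were higher for 9 of 13 (adjusted p = 0.502), with 11.7 reads of the hexose transporter gene Slc2a7 (9.7 in SENS 2) and 9 of Slc5a10 (6 in SENS 3) in SENS and none in NEO.

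Monocyte, neutrophil and border macrophage genes were higher for 16 of 25 (adjusted p = 0.583), among them Ms4a4a with 48.3 ± 118 CPM in NEO and 482 ± 358 CPM in SENS, and Siglec1 with no reads in NEO and 13 in SENS, 8 of them in SENS 3. Major urinary protein genes were higher for 6 of 12 (adjusted p = 0.609), with 30 reads of Mup6 (25 in SENS 6) and 2.95 of Mup12 (2.45 in SENS 4) in SENS and none in NEO. The pooled SENS level of Mup12 was 0.639 times the NEO limit of 3 reads, so its 0 reads in NEO show no difference. T and B lymphocyte genes were lower for 12 of 26 (adjusted p = 0.723), with Cd2 at 891 ± 607 and 359 ± 348 CPM. Cell division genes were lower for 12 of 21 (adjusted p = 0.723). The mitotic kinesin gene Kif18b had 48 reads in 4 NEO libraries and none in SENS (limma adjusted p = 0.745). Its pooled NEO level was 24.6 times the SENS limit of 3 reads, a ratio that leaves out the spread between libraries. NEO 3 held 23 of the 48 reads, and without it the ratio was 14.9. The proliferation marker Mki67 had 226 ± 553 and 946 ± 1086 CPM, with all 10.5 NEO reads in NEO 6. Appetite and metabolic peptides and their receptors were lower for 16 of 31 (adjusted p = 0.724). The relaxin 3 gene Rln3 had 958 ± 341 CPM in NEO and 257 ± 256 CPM in SENS. The neuropeptide FF gene Npff had 48.9 ± 120 and 235 ± 181 CPM, with all 3 NEO reads in NEO 1.

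Striated muscle genes were higher for 13 of 20 (adjusted p = 0.855), with Mybph at 34 reads (32 in SENS 6) and Myl3 at 6 reads in SENS and none in NEO. The pooled SENS level of Myl3 was 1.30 times the NEO limit of 3 reads. Interferon-induced genes were higher for 16 of 30 (adjusted p = 0.970), with Gbp5 at 632 ± 439 and 126 ± 199.6 CPM and Oas1a at 432 ± 458 and 981 ± 473 CPM. Oas1a carried fractional reads, so its value is uncertain. Photoreceptor and lens genes were higher for 9 of 18 (adjusted p = 0.970), with the cone gene Pde6h at 578 ± 416 and 220.5 ± 238 CPM. The opsin gene Opn1sw was at 132 ± 258 and 484 ± 734 CPM, with 36 of its 48 SENS reads in SENS 6. Olfactory receptors were higher for 42 of 72 (adjusted p = 0.970), although camera placed the list lower than other genes (median 0.89, mean 0.18). Olfr315 had no reads in NEO and 11 in SENS, and Olfr920 had 866 ± 922 and 87.4 ± 142 CPM. The lymphocyte (median 0.18), interferon (0.48) and photoreceptor (0.13) lists also had medians above 0 where camera placed them lower than other genes, and the appetite list had a mean above 0 (0.07) where camera did. All CPM values of these lists are means ± SD (n = 6 each).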

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

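In each group of 6 libraries, the library farthest from the rest was compared with the group's range, for 192 groups of values (named genes, library measures and lists). A library stood apart in 46 of them, where chance marks about 1 in 20 groups of normally distributed values. Values as sparse as these do not follow that form, so the number of marks is no measure of an excess. In 11 of the 46 the other 5 libraries were all at 0, so a few reads were enough. Of the tests of explanations below, the summed hepatocyte genes were the only one set before its result was seen; all others were chosen after the results were seen.

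The single libraries that stood apart in NEO held, in CPM, the following gene values. NEO 1 had 1759 for Col14a1, 97.7 for Stag3 and 293 for Npff. NEO 3 had 1259 for Tshb. NEO 4 had 127 for Hba-a1, 416 for Vmn2r5, 761 for Krt86 and 1522 for Il17b. NEO 5 had 289.8 each for Slc4a1 and Ms4a4a and 29.0 for Pou1f1. NEO 6 had 1033 for F13a1, 129 for Ndufs5, 1431 for Vmn2r2, 1356 for Mki67 and 646 for Opn1sw. Summed over lists, NEO 1 was low for blood cell markers, with 391 against 1902 to 2753 in the other NEO libraries. The other list sums that stood apart were high. NEO 1 had 13514 for striated muscle genes, NEO 3 had 12655 for sperm and testis genes, and NEO 6 had 11619 for keratins.

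In SENS the gene values that stood apart, in CPM, were these. SENS 1 had 114 for Vmn2r5. SENS 2 had 5196 for Zic1, 513 for Gbp5 and 622 for Slc2a7. SENS 3 had 1949 for Fgf20 and 75.0 for Grm6. SENS 4 had 372 for Rpl3l and 931 for Nutm1. SENS 5 had 415 for Gys2 and 664 for Cyp2j12. SENS 6 had 710.4 for Snord53, 1366 for Mup6, 1967 for Opn1sw, 1749 for Mybph, 1639 for Tex47 and 5246 for Gnrh1. Summed over lists, SENS 5 had 7654 for keratins and 12790.2 for cell division genes, and SENS 6 had 7978 for photoreceptor and lens genes.

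SENS 4 stood apart for Prl (4842 CPM), Mup12 (228 CPM), the summed pituitary markers (9796 CPM) and the summed major urinary proteins (4002 CPM). It held 33 reads of the growth hormone gene Gh, 52 of Prl and 80 of the albumin gene Alb, where the other 11 libraries held at most 2, 1 and 11. Liver RNA in this library, or reads from a liver library, is a candidate explanation for Alb and the major urinary proteins. Of 57 other hepatocyte genes with reads, 17 had their highest CPM in SENS 4 and at most 6 in any other library, while 8.07% of all genes peaked there. Of the 57, 49 also had reads in other libraries, while Ahsg (7 reads) and Cyp3a11 (6 reads) had reads in SENS 4 alone. Their summed CPM was 1.63 times the median of the other libraries, between the bounds set beforehand (3 and 1.5), and NEO 1 came close (12590 against 12949.8 CPM), so that test decided nothing. Pituitary RNA could account for Gh and Prl and stays open: 6 other pituitary genes summed to 0 CPM in SENS 4, but these have low expression and few were measured. No biological explanation of the food cue was tested for a pattern in 1 library.

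SENS 6 stood apart in having the fewest genes at an equal number of table reads (1152 genes in 6000 thinned reads, against 1639 to 1827 in the other SENS libraries), the most reads per gene above 0 (median 6) and the largest share of fractional values (23.8%). A few genes taking most of the reads is argued against, since its 10 highest genes held 4.86% of the reads and those of SENS 2 held 6.69%. Copies of few starting molecules could give the median of 6 reads per gene, which was at most 4 elsewhere. Without molecular identifiers this cannot be told apart from fewer genes being expressed.

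The larger number of reads in the table in SENS libraries could come from deeper sequencing or from a larger share of reads in these genes, and an effect of the food cue on that share stays open. The mean number of genes above 0 was higher by 243 in SENS, as deeper sampling would give, but within the spread between libraries. At an equal number of table reads the difference was 49.0 genes. The total reads of the libraries are not used here, so these explanations cannot be told apart.

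Other groupings of the same 12 libraries show how much chance gives; 100 of the 462 splits were drawn, the real one included. For the 189 genes at an unadjusted p under 0.05, 24 of the 100 splits gave as many, with 284 in the highest other. For the 3 calls among the added lists, 16 of the 100 splits gave as many, with 6 in the highest other. Chance was not excluded for either. For the adjusted gene calls and the lists set beforehand the real count was 0, which all 100 splits reach whatever they hold (highest other 0 genes and 2 lists), so the splits say nothing about chance there.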

How the results depend on the processing

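The limma count of 0 genes held in all 29 other fits (189 genes at an unadjusted p under 0.05, and 0 at an adjusted p under 0.1). The smallest adjusted p lay between 0.177 (without SENS 3) and 0.791 where single libraries were left out. The unadjusted count was 101 with a mean of at least 200 CPM, a fit of fewer genes (1716), and 168 to 208 with each library left out. With the replicate block the adjusted count was 0, the unadjusted count 176, and 3 added lists were called. Replicate numbers are not shown to pair libraries (r of same-numbered deviations between −0.03 and 0.11, and best matches mostly with other numbers). The 3 added list calls became 4 with pseudocounts of 50, 100 and 200 and with quantile scaling, each time with sperm and testis genes added. They became 0 with a mean of at least 200 CPM, 0 with an estimated correlation and 0 with fry (which called sperm and testis genes with a mean of at least 100 or 200 CPM), 1 without NEO 4 and SENS 6, and 1 to 4 with each library left out; the cause was not tested. Lists set beforehand gave 0 throughout, and none had enough members at a mean of at least 200 CPM. Camera and fry did not use the variance model, so the fits without a variance trend or with robust variance are no check of their calls. Fry also did not use the library weights.

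The log2 difference of Fosl1 turned from −0.73 to 1.09 without NEO 4 and SENS 6, and ranged from −1.89 to 0.29 with each library left out. Tshb (−1.87) turned to 0.069 and 0.19 with pseudocounts of 100 and 200, and Gnrh1 (−0.74) to 0.13, 0.24 and 0.31 with pseudocounts of 50, 100 and 200. Gnrh1 ranged from −2.24 to 0.61 and Cd52 from −1.74 to 0.43 with each library left out (highest without SENS 1). The 67 named genes other than Gys2 and Fosl1 kept their direction in 1889 of 1897 comparisons, none past the threshold. Genes at 0 in every library of a group, such as Kif18b, could hardly turn, and many others were chosen for small p-values in these data. The count is thus no measure of stability. Gys2 ranged from 1.45 to 1.74 with each library left out, with no value without SENS 5, its one library with reads, and from 0.27 (pseudocount of 200) to 2.00 (pseudocount of 0.1) over all settings. With each library left out, mean marker levels ranged from −0.40 to 0.55 (blood cells; 0.68 without NEO 4 and SENS 6) and from −0.22 to 0.97 (pituitary, lowest without SENS 4), and the exact permutation p stayed at 0.247 or above in all settings. The difference in reads in the table was 4595 with libraries paired by replicate number (exact permutation p = 0.0625), and 3556 to 5492 with each library left out. The difference in genes at an equal number of table reads (49.0) ranged from −26.3 (without NEO 4) to 148, and that in the share of fractional values from −1.19 to 0.28 percentage points. That in the median reads per gene above 0 (0.908) reached an unadjusted exact permutation p = 0.0476 without SENS 1 or SENS 5. The median log2 difference of all genes (0.39) ranged from 0.29 to 0.72 with each library left out (highest without NEO 2). It was 0.52 with trimmed-mean scaling, 0.12, 0.081 and 0.051 with pseudocounts of 50, 100 and 200, and −0.055 with a mean of at least 200 CPM. The edgeR test planned for raw counts was not run, since the table holds CPM and 18.8% of its values above 0 were not whole reads. A count model on rounded reads was not tried. With the spread of these libraries, 6% of simulated 16-fold changes were recovered (4703 genes, SENS against NEO). With counting noise alone it was 81% (4760 genes), where 33 of 195 calls were unchanged genes, whose CPM the rescaling of columns had shifted.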

Other observations

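In the genes of this table the spread between libraries was far above counting noise. Among genes with a mean of 2 to 5 reads, the median ratio of variance to mean was 5.60, where counting noise alone gives about 1. It was lower among genes with fractional reads (4.37) than among genes counted in whole reads (5.87), and the same order held at 5 to 10 reads (5.56 and 7.65). The ratios used reads not scaled to library totals. Pearson's r between libraries ranged from −0.09 to 0.27, on log2(CPM + 100) over genes with a mean of at least 200 CPM. These genes are not independent replicates. No gene had 10 or more reads in 9 or more libraries. The selection of genes could thus itself raise the ratios and lower r (not tested).

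Large read numbers of single genes often lay in 1 library, which the selection of genes could favour (not tested). Tspan8, a tetraspanin, had 159 reads in SENS 2, the highest value of the table. SENS 6 held 122 reads of the kallikrein gene Klk6, 104 of the sperm ion channel gene Catsperg1 and 96 of Gnrh1, which encodes gonadotropin-releasing hormone; Gnrh1 had at most 15 reads in any other library. The mean of Gnrh1 was 510.3 ± 425 CPM in NEO and 1269 ± 2014 CPM in SENS (SD, n = 6 each), while its log2 fold change was −0.74 (limma adjusted p = 0.902). Tshb, also a gene of the pituitary stalk next to the arcuate nucleus, had 31 reads in SENS 3, 15 in SENS 4 and 9 in NEO 3.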
